A study of Mus musculus with 12 samples.

How the data were processed

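RNA was measured in mature B cells sorted from the bone marrow of C57BL/6 mice by the surface proteins B220 (high), IgM (present) and CD93 (absent). There were 4 groups of 3 libraries, 12 in all: young wild type (9, 10 and 11 weeks of age), old wild type (98, 99 and 100 weeks), and a pair of Bak1-deficient groups of 10 weeks. In the first of these the Bax gene was flanked by loxP sites but intact, and the cells are called apoptosis-sensitive here. In the second Bax had been deleted, and the cells are called apoptosis-resistant. Groups and replicate numbers were taken from the sample labels. The series design describes the 3 libraries of a group as biological replicates. Per the labels' protocols, RNA was isolated with a Qiagen kit and polyadenylated RNA was made into libraries with the Illumina TruSeq RNA v2 kit.

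The values used were whole-number read counts per gene, as the authors deposited them in 1 table with 1 column per sample. Per the submitters' processing notes, Subread and featureCounts were used with the mouse build mm10. Tool versions, the gene annotation, the strand setting and any filter were not given in the sources used here. The table named genes by Entrez gene number and held 27179 genes, of which 6753 had a count of 0 in every library and 260 were immunoglobulin genes. Symbols and coordinates came from the RefSeq annotation of GRCm38.p6, which matched 25275 of the genes. The other 1904 had no symbol and were tested but not named. The table had 0 columns that were not used.

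Because strand was not given, reads of overlapping and antisense genes were uncertain, and so was the division of reads among near-identical copies such as the Bcl2a1, globin, ribosomal protein, Ifit and Vmn2r genes. The gene-level count of Bax also takes reads from parts of the gene that were not deleted. The deleted exons were not given in the sources used here.

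Total counts per library ran from 13474162 to 23539764. Library factors were computed with the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3. Genes were kept by edgeR's filterByExpr with its minimum of 10 reads, which left 13592 genes, 408 of them without a symbol. All 12 libraries were fitted together by group with edgeR's robust quasi-likelihood test, which left 8 residual degrees of freedom. P values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. An adjusted p without another tool's name is from this test. Levels are given as CPM, a gene's share of its library's counts after TMM on the usual CPM scale, as mean ± SD over 3 libraries. Log2 fold changes are given ± SE.

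The comparisons were old against young wild type, apoptosis-resistant against apoptosis-sensitive cells, and the difference between these effects (age effect minus genotype effect). Apoptosis-sensitive against young wild-type cells was compared for context, since these groups shared no collection date. The age and genotype comparisons shared no library. Their fold changes were compared by a correlation across genes and by the overlap of calls, set against the overlap of independent lists. The p of the correlation was the share of 100 splits of the libraries into groups of 3 with a correlation as large, two-sided.

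The lists fixed in advance were 24 gene lists and 9 marker lists of other cells, with 567 genes, of which 3 were not in the table and 538 were tested. The gene lists were anti-apoptotic BCL-2 family, pro-apoptotic BCL-2 family and caspase cascade (without Bax and Bak1), p53 targets (without Bax), age-associated B cell, memory B cell, marginal zone, B-1, follicular and resting, germinal centre, immature and precursor, and plasma cell genes, class-switched immunoglobulin constant regions, cell cycle, interferon-stimulated, NF-kB target, immediate early, B cell receptor signalling, BAFF receptor signalling, MHC class II, oxidative phosphorylation, cytosolic ribosomal protein, unfolded protein response, senescence and inflammatory, and homing and adhesion genes. The marker lists were T cell, NK cell, granulocyte, monocyte and macrophage, erythroid, megakaryocyte, plasmacytoid dendritic cell, bone marrow stromal and sex-linked genes. Each was tested with camera (limma 3.58.1) at the preset correlation between genes of 0.01, adjusted over the lists. Camera compares a list with all other genes. It was rerun with an estimated correlation, and fry was run, which tests whether a list's genes moved on balance in 1 direction.

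Named genes followed a fixed rule. Bax and Bak1 were named first. For each main comparison, the 8 largest rises and 8 largest falls were named among genes that passed the threshold, had a mean of at least 1 CPM over the 6 libraries and moved the same way in all 3 date pairs. Immunoglobulin and T cell receptor variable, diversity and joining segments, predicted genes and genes without a symbol were left out and only counted. If fewer than 10 passed, all were named, then others by p up to 10 as not passing. For each list, up to 4 called members with the smallest p were named, or up to 2 members as values where none passed. The 5 genes with the smallest adjusted p for the difference and up to 10 genes called in both comparisons were added.

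Same-numbered libraries shared a collection date within the wild-type set (24 March, 11 April and 12 April) and within the Bak1-deficient set (30 May, 31 May and 7 May), per the labels. The numbers therefore paired the samples. The labels gave the year as 2006 for both libraries of 24 March and as 2016 for all others, which may be a typing error and was not resolved. Dates were read in the order year, day, month, so 7 May would be 5 July if read the other way. Neither doubt alters which libraries shared a date. After subtraction of group means, libraries of the same date had correlations of 0.745, 0.512 and 0.555 in wild type and 0.284, 0.325 and 0.487 in the Bak1-deficient set, against -0.618 to 0.373 for other pairs. The date was not a term of the fit reported first. A fit with the date as a block left 4 residual degrees of freedom.

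Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts the ratio has a 95% counting interval (exact binomial). Fitted fold changes of such genes depend on the prior count and give no bound. Reads came from PCR libraries without molecular identifiers, so intervals and floors cover counting error only.

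The fit was tested on simulated data drawn from the means and spread of the fit with the date block, at the real library sizes. In each comparison 100 genes were changed at each fold size. Date effects were thus part of the simulation. Its higher recovery with the block was in part built in and is no test of the block on the real data. For age (13163 genes), 15% of genes changed by a log2 fold of 1 and 76% of those changed by 2 were called without the block, and 76% and 94% with it. For genotype (13160 genes) the shares were 11% and 59% without the block, and 73% and 95% with it. Without the block 0% of calls were false in these simulations. With it 9.1% were false for age and 7.2% for genotype.

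The lists, comparisons, named-gene rule and the following alternatives were chosen before the data were examined: relative log expression (RLE) and upper-quartile factors, DESeq2 1.42.0, limma-voom, no count filter, a filter of at least 1 CPM in at least 3 libraries, only the 6 libraries compared, the date as a block, immunoglobulin genes left out, and each library left out in turn. Chosen after seeing the data were fits without both libraries of 24 March or of 7 May, with and without the block, and DESeq2, limma-voom or RLE factors together with the block.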

Results

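RNA was counted per gene in mature B cells of mouse bone marrow, sorted as B220 high, IgM positive and CD93 negative, from young wild-type, old wild-type, apoptosis-sensitive Bak1-deficient and apoptosis-resistant Bak1-deficient mice, with 3 libraries in each of the 4 groups. BAK1 and BAX are the effector proteins that permeabilise the outer mitochondrial membrane in apoptosis. Cells that lack both cannot take this route, while cells that lack BAK1 alone still can. Total counts were 13474162, 23539764 and 15443934 in young wild type, 19095927, 19147890 and 18324504 in old wild type, 17710504, 17381722 and 20760533 in apoptosis-sensitive cells, and 14785100, 16659356 and 20136658 in apoptosis-resistant cells. Between 15253 and 17245 genes had a count in each library. Immunoglobulin genes took 0.91% to 2.58% of the counts, mitochondrial genes 1.62% to 3.46%, and the 10 most abundant genes 4.58% to 6.23%. Replicates of a group had correlations of log CPM from 0.929 to 0.991, and every pair differed by more than counting noise. The first principal component, with 31.9% of the variance, set the pair of libraries collected on 24 March (young replicate 1 and old replicate 1, whose labels give 2006 as the year) apart from the other 10, whose labels give 2016.

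The targeted genes were examined first. Bax (Entrez gene 12028, GRCm38.p6 chromosome 7, 45461695 to 45466903) had 988, 957 and 2141 reads in apoptosis-sensitive cells and 72, 106 and 175 reads in apoptosis-resistant cells. Its level was 67.1 ± 27.4 CPM in young wild type, 62.7 ± 24.1 in old wild type, 70.7 ± 25.5 in apoptosis-sensitive and 6.58 ± 1.70 in apoptosis-resistant cells (SD, n = 3 each). Bax thus fell between the apoptosis groups by 3.42 ± 0.40 on the log2 scale (adjusted p = 0.0135). This call was lost without apoptosis-sensitive replicate 1 (adjusted p = 0.054) and without apoptosis-resistant replicate 1 (0.124), 2 (0.117) or 3 (0.0726), while the log2 fold change stayed between -3.62 and -3.25 in these fits. Bak1 (Entrez gene 12018, chromosome 17, 27019812 to 27028627) had 40.1 ± 8.1 CPM in young wild type, 35.5 ± 10.4 in old wild type, 9.43 ± 3.15 in apoptosis-sensitive and 10.7 ± 3.72 in apoptosis-resistant cells. The log2 fold change of Bak1 between apoptosis-sensitive and young wild-type cells was -2.09 ± 0.34 and did not pass the threshold in edgeR (adjusted p = 0.135). DESeq2 called it (adjusted p = 6.2e-06). Neither gene passed the threshold between old and young wild type, with log2 fold changes of -0.10 ± 0.36 for Bax and -0.18 ± 0.33 for Bak1.

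**Figure D1:**
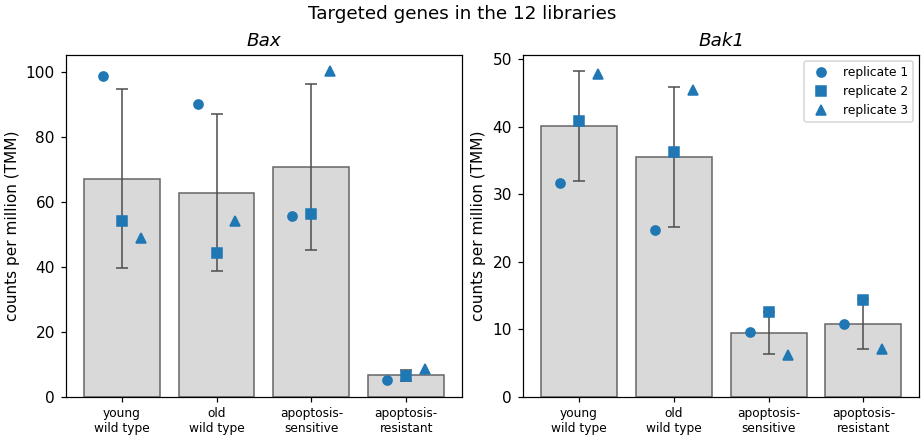
Normalised counts (CPM) of Bax and Bak1 in each library of the 4 groups, with bars at the group mean, error bars of 1 SD (n = 3) and points for single libraries. Bax averaged 6.58 CPM in the apoptosis-resistant group against 62.7 to 70.7 in the others, and Bak1 averaged 9.43 and 10.7 CPM in the Bak1-deficient groups against 35.5 and 40.1 in wild type.

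The comparison of old with young wild type asks what age changes in bone marrow mature B cells. Genes known from age-associated B cells, a population that accumulates in old mice, were higher in old cells. Of these, 10 of 18 rose and 0 fell (camera adjusted p = 6.13e-31, and 0.004 with an estimated correlation). With the date block the adjusted p was 0.159 for camera with an estimated correlation and 0.0121 for fry. Fcrl5 (Entrez gene 329693, chromosome 3, 87435777 to 87500678), an Fc receptor-like protein of the B cell surface, rose from 21.8 ± 2.47 to 77.8 ± 12.5 CPM, and Itgax, which encodes the integrin CD11c, rose from 0.845 ± 0.811 to 15.7 ± 8.20 CPM. Nt5e, which encodes the surface nucleotidase CD73, rose from 2.69 ± 1.10 to 54.2 ± 26.0 CPM. Genes of immature and precursor B cells were lower as a list, where 3 of 15 fell (camera adjusted p = 5.9e-11, and 0.101 with an estimated correlation), with Cd93, whose protein was excluded in the sort, at 32.4 ± 3.45 CPM in young and 12.1 ± 2.22 in old cells. Bmf, a pro-apoptotic BH3-only gene, fell from 79.2 ± 26.2 to 19.1 ± 7.35 CPM.

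Of 13592 genes tested, 273 changed with age, 231 higher and 42 lower in old cells, and 84.6% of the calls were higher. The spread behind these calls came from all 12 libraries. Wild-type replicates had correlations of log CPM from 0.929 to 0.981, and Bak1-deficient replicates from 0.963 to 0.991. Fits of only the 6 libraries compared, with fewer degrees of freedom, called 1 gene for age and 5 for genotype. With the collection date as a block 2028 genes were called, 1073 higher and 955 lower, so that 52.9% were higher. The largest rises came from genes with almost no reads in young cells. The prostaglandin transporter gene Slco2a1 was at least 45.6-fold higher in old cells (adjusted p = 0.0108), the potassium channel gene Kcnt2 at least 43.8-fold higher (0.0208) and Bpifb4 at least 35.5-fold higher (0.0259), each with 0 reads in young cells. The ratio was 96.1 for Ttll7, a tubulin-modifying enzyme (95% counting interval 26.3 to 798, adjusted p = 0.00709), 80.9 for Ccn2, a matricellular protein (22.1 to 673, 0.0229), and 63.7 for Cyb5r2 (21.5 to 311, 0.00932). Igfn1 rose by a log2 fold change of 7.16 ± 0.83 (adjusted p = 0.00323). Igha, the constant region of IgA, rose by 5.93 ± 1.28 (adjusted p = 0.0385, and 0.0614 with the date block), with 128, 4269 and 482 CPM in the old libraries against 6.82, 36.3 and 36.5 in the young. The largest falls were those of Fcamr, an Fc receptor for IgA and IgM (-3.76 ± 0.62, adjusted p = 0.0112), the Wnt ligand genes Wnt10b (-3.75 ± 0.75, 0.0288) and Wnt10a (-2.97 ± 0.42, 0.00648), and the collagen gene Col5a3 (-3.43 ± 0.74, 0.0392, and 0.0529 with the block). Tmc7 (-2.95 ± 0.57, 0.0252), Rapgefl1 (-2.89 ± 0.53, 0.0216), the microtubule gene Map2 (-2.77 ± 0.52, 0.022) and the transcription factor gene Sox4 (-2.24 ± 0.37, 0.0112) followed. A further 11 called genes that were higher and 1 that was lower had no symbol or only a predicted name.

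Among B cell lists, 10 of 18 age-associated B cell genes rose with age and none fell (14 rose when adjusted over the list alone), with a median log2 fold change of 1.91 (camera adjusted p = 6.13e-31, and 0.004 with an estimated correlation). Fcrl5 rose by 1.84 ± 0.17 (adjusted p = 0.001), Cd80, a costimulatory ligand, by 2.86 ± 0.40 (0.00563), the chemokine receptor gene Ccr1 by 2.09 ± 0.31 (0.00709) and Itgax by 4.22 ± 0.67 (0.01). Of 13 B-1 cell genes 4 rose and 0 fell (6 rose when adjusted over the list alone), with a median of 1.08 (camera adjusted p = 1.36e-08, and 0.004 with an estimated correlation). These were Zbtb32 (2.64 ± 0.43, adjusted p = 0.0109), the phosphatase gene Ptpn22 (1.20 ± 0.22, 0.0194), Bhlhe41, a transcription factor of B-1 cells (1.81 ± 0.34, 0.0224), and Plscr1 (1.66 ± 0.38, 0.048). Of 13 memory B cell genes Nt5e and Cd80 rose (3 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 0.000278, and 0.17 with an estimated correlation). Zbtb32, Bhlhe41 and Itgam are on both the B-1 and the age-associated list, and Cd80 is on both the memory and the age-associated list. The results of these lists are therefore not independent. Of 15 immature and precursor genes Cd93 (-1.43 ± 0.19, adjusted p = 0.00514), Sox4 and Lef1 (-1.86 ± 0.35, 0.0229) fell and 0 rose (7 fell when adjusted over the list alone). The median of that list was -1.43 (camera adjusted p = 5.9e-11, and 0.101 with an estimated correlation). Of 16 follicular and resting genes the complement regulator Cd55 fell, from 848 ± 46.5 to 469 ± 52.9 CPM, and 15 did not pass (1 fell when adjusted over the list alone). The median was -0.36 (camera adjusted p = 0.000423, and 0.17 with an estimated correlation). A block for the date gave 11 age-associated B cell genes as higher, 8 of these 16 as lower, 10 immature and precursor genes as lower, and 7 B-1 and 4 memory genes as higher, and 1 memory gene as lower.

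**Figure D2:**
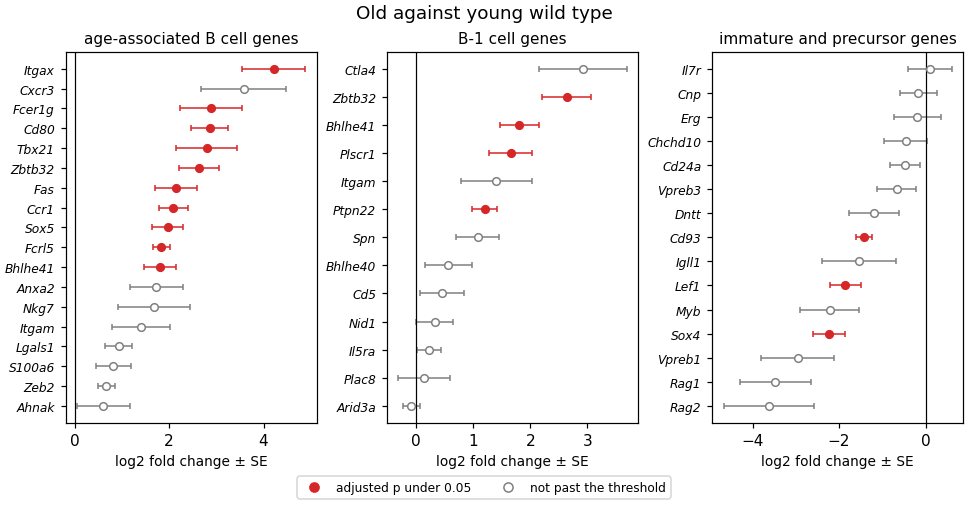
Log2 fold change ± SE, old against young wild type (3 libraries each), of every tested gene of the age-associated B cell, B-1 cell and immature and precursor B cell lists, with filled red points for adjusted p under 0.05. Median log2 fold changes were 1.91, 1.08 and -1.43.

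Lists of antibody and effector genes were also called with age at the preset correlation, but not with an estimated one. Of 17 plasma cell genes 1, Igha, rose (3 adjusted over the list alone), with a median of 0.71 (camera adjusted p = 0.000278, and 0.48 with an estimated correlation). Their pair medians were 0.79, 1.32 and -0.17, so the date pairs did not all go the same way. The 6 class-switched constant regions, with Igha again the 1 that rose and 5 adjusted over the list alone, had a median of 3.29 (5.74e-07, and 0.101 with an estimated correlation). Of 13 senescence and inflammatory genes the chemokine genes Ccl5 (3.55 ± 0.75, adjusted p = 0.0362) and Cxcl10 (4.81 ± 1.10, 0.0486) rose (4 adjusted over the list alone), with a median of 0.74 (camera adjusted p = 0.00259, and 0.17 with an estimated correlation). No single member passed in 3 further lists with lower medians, which were 33 cell cycle genes (median -0.35, camera adjusted p = 0.0156), 19 immediate early genes (-0.66, 0.0283) and 77 ribosomal protein genes (-0.22, 0.00793). Each of these 3 list calls was lost with an estimated correlation (adjusted p = 0.731). With the block 3 cell cycle, 2 immediate early and 2 ribosomal protein genes fell, 1 plasma cell gene and 1 constant region rose, and 4 senescence genes rose and 1 fell.

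Markers of other cells moved with age alongside these lists. Of 11 T cell markers Cd3g (4.05 ± 0.76, adjusted p = 0.0227) and Tcf7 (1.84 ± 0.39, 0.0378) rose (9 adjusted over the list alone), with a median of 2.31 (camera adjusted p = 2.92e-11, and 0.0499 with an estimated correlation). Of 4 NK cell markers Ncr1 rose, with a ratio of 22.2 (95% counting interval 7.32 to 110), and all 4 did when adjusted over the list alone (median 2.24, camera adjusted p = 7.37e-06, and 0.0162 with an estimated correlation). The macrophage gene Adgre1 rose from 6.87 ± 3.55 to 34.9 ± 14.6 CPM among 10 monocyte and macrophage markers (4 adjusted over the list alone), whose median was 1.66 (1.98e-05, and 0.182 with an estimated correlation). The stromal chemokine gene Cxcl12 rose from 4.45 ± 4.37 to 61.8 ± 48.2 CPM among 7 stromal markers (5 adjusted over the list alone), with a median of 3.13 (1.55e-06, and 0.17 with an estimated correlation). Ccr9 rose by 1.49 ± 0.32 (adjusted p = 0.0385) among 5 plasmacytoid dendritic cell markers (3 adjusted over the list alone), with a median of 0.57 (0.0038, and 0.164 with an estimated correlation). Under the date block the genes that rose numbered 6 for T cell, 4 for NK cell, 6 for monocyte, 6 for stromal and 3 for plasmacytoid dendritic cell markers. Summed per library, stromal markers reached 21.6, 99.9 and 170.5 CPM in old cells against 3.2, 8.2 and 23.9 in young, and monocyte markers 62.6, 138.7 and 226.1 against 35.7, 28 and 150. T cell markers reached 84.2, 55.2 and 65.3 against 76.2, 37.6 and 40.7, NK cell markers 6.3, 12.5 and 13.8 against 1, 3.3 and 4.4, and plasmacytoid dendritic cell markers 59.3, 76.3 and 72.4 against 42.6, 53.4 and 48.3. No list call with age held with an estimated correlation once the date block was fitted (lowest adjusted p = 0.107).

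The remaining 17 lists were not called with age. Fas, the death receptor, rose by 2.15 ± 0.44 (adjusted p = 0.0318) and is on the pro-apoptotic, p53 target and germinal centre lists, whose camera adjusted p values were 0.64, 0.847 and 0.266. Bmf (-2.05 ± 0.33, adjusted p = 0.0105) fell on the pro-apoptotic list, where the other 14 genes did not pass. Of 27 interferon-stimulated genes (camera adjusted p = 0.285) Cxcl10 rose and Oasl1 fell from 22.3 ± 5.16 to 9.77 ± 1.29 CPM. Of 17 homing genes (0.89) the integrin gene Itgb1 rose by 1.68 ± 0.38 (adjusted p = 0.0488). No member passed for anti-apoptotic (0.153), marginal zone (0.348, with 5 higher when adjusted over the list alone), NF-kB target (0.988), B cell receptor (0.177), BAFF receptor (0.285), MHC class II (0.77), oxidative phosphorylation (0.285) and unfolded protein response genes (0.983). The same held for granulocyte (0.199, and 0.0169 with the date block, where an estimated correlation gave 0.659), erythroid (0.981), megakaryocyte (0.153) and sex-linked genes (0.285). The date block called members of most of these 17 lists, which rose and fell in mixed numbers. There 2 pro-apoptotic genes rose and 3 fell, as did 3 and 2 p53 targets, 1 and 2 germinal centre, 5 and 4 interferon-stimulated, 3 and 2 homing, 4 and 3 marginal zone (5 and 6 over the list alone), 4 and 2 NF-kB target and 1 and 2 B cell receptor genes. In the same fit 2 anti-apoptotic genes, 2 granulocyte and 1 megakaryocyte markers rose, 2 BAFF receptor, 1 MHC class II and 1 sex-linked gene fell, and 0 passed in the other 3 lists. Fcrl5, Cd80, Ccr1, Itgax, Nt5e, Cd93, Sox4, Bmf, Wnt10a, Igfn1, Ttll7 and Cyb5r2 kept their calls without any single library, and every other gene named as changed with age lost its call without at least 1, with highest adjusted p values from 0.0504 for Slco2a1 to 0.188 for Cxcl10. In DESeq2 735 genes changed with age, and 1 did when only the 6 wild-type libraries were fitted. The count was 165 and 75 without young replicate 1 or 2, 86 and 160 without old replicate 2 or 3, and fell by over 1.5 times without young replicate 3 as well. Without young replicate 2, 68% of calls were higher.

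The comparison of apoptosis-resistant with apoptosis-sensitive cells asks what loss of BAX changes in B cells that already lack BAK1. Besides Bax, 5 genes passed the threshold. Bbc3 (Entrez gene 170770, chromosome 7, 16308398 to 16318334), which encodes the pro-apoptotic BH3-only protein PUMA and is a p53 target, rose from 5.91 ± 2.05 to 33.3 ± 11.7 CPM. Trib3 (Entrez gene 228775, chromosome 2, 152337425 to 152344060) and Atf5, both known from the integrated stress response, rose from 1.07 ± 0.05 to 8.44 ± 2.09 CPM and from 9.86 ± 1.10 to 28.8 ± 6.69 CPM. Ccnd2, the gene of the G1 cyclin D2, fell from 123 ± 12.2 to 28.8 ± 3.40 CPM, and the Wnt ligand gene Wnt10a (Entrez gene 22409, chromosome 1, 74792019 to 74804176) fell from 19.1 ± 10.6 to 1.96 ± 0.29 CPM. As lists, p53 targets were higher in the resistant cells (camera adjusted p = 2.28e-10, and 0.00503 with an estimated correlation). NF-kB targets (2.86e-10, and 0.00748 with an estimated correlation) and cell cycle genes (7.19e-31, and 0.0785 with an estimated correlation) were lower. With an estimated correlation and the date block the camera adjusted p values were 0.104, 0.113 and 0.115, and none passed. That fit left 4 residual degrees of freedom, and no list in any comparison passed this test. Failing it therefore does not show that a list was unchanged. With fry in the same fit the adjusted p values were 0.0132, 0.0132 and 0.0172.

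In all, 6 of 13592 genes changed, 3 higher and 3 lower, and 666 had an unadjusted p under 0.05. Log2 fold changes were 2.97 ± 0.33 for Trib3 (adjusted p = 0.0135), 2.49 ± 0.34 for Bbc3 (0.0395), 1.55 ± 0.23 for Atf5 (0.0449), -3.28 ± 0.43 for Wnt10a (0.029) and -2.09 ± 0.31 for Ccnd2 (0.0449). Atf5 lies 645037 bases from Bax. The next 4 genes by p did not pass. These were the ubiquitin ligase gene Nedd4 (-1.77 ± 0.27, adjusted p = 0.0598, and 0.00166 with the date block), the growth factor gene Tgfa (5.47 ± 0.85, 0.0598, and 0.000199 with the block), the cell cycle inhibitor gene Cdkn1a (2.19 ± 0.36, 0.0843, and 0.0022 with the block) and the ferritin gene Ftl1 (-2.01 ± 0.34, 0.1), which lies 1809 bases from Bax. Of 131 tested genes within 10 Mb of Bax 6 had p under 0.01 here, 4.58%, against 1.76% elsewhere (ratio 2.6, one-sided Fisher's exact test p = 0.0304), and near Bax or Bak1 the shares were 2.69% and 1.75% (ratio 1.54, 0.0844). These tests were chosen after the values were seen. With the date block 463 genes were called, 195 higher and 268 lower, among them all 6 named calls, and DESeq2 without the block called 127. Leaving out sensitive replicate 1, 2 or 3 left 0, 2 and 5 edgeR calls, and leaving out resistant replicate 1, 2 or 3 left 1, 1 and 0. Each of the 6 calls was lost without at least 1 library, with adjusted p values up to 0.281 for Ccnd2, 0.228 for Atf5, 0.227 for Bbc3, 0.182 for Wnt10a and 0.0966 for Trib3.

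Of 22 p53 target genes tested, Bbc3 rose and 21 did not pass (6 rose when adjusted over the list alone), with a median log2 fold change of 0.21 (camera adjusted p = 2.28e-10, and 0.00503 with an estimated correlation). Under the date block 7 of them rose. Of 19 NF-kB target genes 0 passed over all genes and 4 fell when adjusted over the list alone, with a median of -0.46 (camera adjusted p = 2.86e-10, and 0.00748 with an estimated correlation). Bcl3 had a log2 fold change of -0.91 ± 0.16 (adjusted p = 0.1, and 0.00342 with the date block) and Nfkb2 of -0.77 ± 0.21 (0.395, and 0.00342 with the block), and 6 of the list fell with the block. Of 33 cell cycle genes 0 passed over all genes and 19 fell when adjusted over the list alone, with a median of -1.11 (camera adjusted p = 7.19e-31, and 0.0785 with an estimated correlation). The transcription factor gene E2f1 had -1.68 ± 0.39 (adjusted p = 0.238, and 0.000808 with the block) and the thymidylate synthase gene Tyms -1.71 ± 0.45 (0.35, and 0.0166 with the block), and 20 of the list fell with the block. Lower medians were seen in every date pair for cell cycle (-1.56, -0.94 and -0.85) and NF-kB target genes (-0.33, -0.51 and -0.48), and higher medians for p53 targets (0.36, 0.16 and 0.30).

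**Figure D3:**
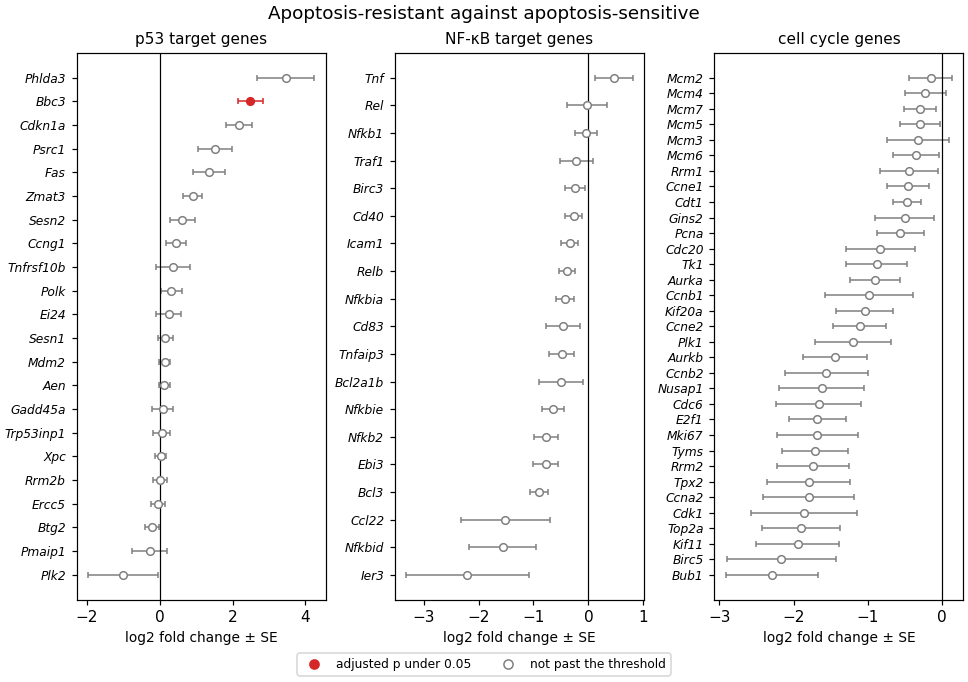
Log2 fold change ± SE, apoptosis-resistant against apoptosis-sensitive cells (3 libraries each), of every tested p53 target, NF-kB target and cell cycle gene, with filled red points for adjusted p under 0.05. Median log2 fold changes were 0.21, -0.46 and -1.11.

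The BCL-2 family lists were examined next. Of 16 pro-apoptotic genes Bbc3 rose and 15 did not pass (4 rose when adjusted over the list alone). The list was called higher (camera adjusted p = 0.000226, and 0.0785 with an estimated correlation) although its median was -0.02, and its mean was 0.35. Of 7 anti-apoptotic genes 0 passed and 2 fell when adjusted over the list alone, with a median of -0.32 (0.00205, and 0.0734 with an estimated correlation). Bcl2 had -0.90 ± 0.21 (adjusted p = 0.23, and 0.00373 with the date block) and Mcl1 -0.59 ± 0.18 (0.485, and 0.0106 with the block). In that fit 4 pro-apoptotic genes rose and 2 anti-apoptotic genes fell.

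No single member passed in the 10 other lists that were called by genotype. Germinal centre genes (11) had a median of 1.79 (camera adjusted p = 3.08e-14, and 0.0734 with an estimated correlation), with 7 higher when adjusted over the list alone and pair medians of 0.68, 0.59 and 3.48. Memory genes had a median of 0.20 (0.000711, and 0.188 with an estimated correlation) with 3 higher over the list alone. Class-switched constant regions had 1.22 (0.00518, and 0.329 with an estimated correlation), and the call was lost with the date block (0.115). Their pair medians were -0.11, -0.50 and 3.64, so the rise came from the pair of 7 May, and the direction turned without it (camera adjusted p = 0.536). Lower medians were found for immature and precursor genes (-0.51, 0.000102, and 0.291 with an estimated correlation, 2 lower over the list alone), immediate early genes (-1.31, 0.00632, and 0.658 with an estimated correlation) and granulocyte markers (-2.41, 6.02e-07, and 0.329 with an estimated correlation). The immediate early pair medians were -0.11, 0.19 and -1.84, and the direction of that list turned without sensitive replicate 3 (camera adjusted p = 0.00251) and without the pair of 7 May (0.857). Lower medians were also found for erythroid markers (-1.73, 0.00113, and 0.5 with an estimated correlation), B-1 genes (-0.43, 0.00858, and 0.0785 with an estimated correlation), BAFF receptor genes (-0.10, 0.0433, and 0.15 with an estimated correlation) and NK cell markers (-1.28, 0.00921, and 0.0785 with an estimated correlation). Adjusted over the list alone, 1 B-1 and 1 BAFF receptor gene fell and 1 constant region rose. The last 3 list calls were lost with the date block (adjusted p = 0.08 for B-1, 0.0722 for BAFF receptor and 0.08 for NK cell genes). Under the block 2 germinal centre and 1 memory gene rose, and 4 immature and precursor, 2 granulocyte, 1 erythroid and 2 BAFF receptor genes fell. Granulocyte markers summed to 872.3, 94.2 and 159 CPM in the sensitive libraries against 84.2, 36.3 and 78.2 in the resistant, and erythroid markers to 405.5, 80.9 and 198.5 against 171.9, 102.6 and 113.5.

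The remaining 18 lists were not called by genotype, and among their members 1 gene passed, Trib3 on the unfolded protein response list (camera adjusted p = 0.237). Camera adjusted p values were 0.299 for age-associated B cell, 0.106 for marginal zone, 0.144 for follicular and resting, 0.563 for plasma cell and 0.199 for interferon-stimulated genes. They were 0.975 for B cell receptor, 0.294 for MHC class II, 0.329 for oxidative phosphorylation, 0.638 for ribosomal protein, 0.114 for senescence and 0.563 for homing genes. Among markers they were 0.106 for T cells, 0.522 for monocytes, 0.16 for megakaryocytes, 0.977 for plasmacytoid dendritic cells, 0.904 for stromal cells and 0.975 for sex-linked genes. When the date was a block, 2 age-associated B cell genes rose and 1 fell, as did 1 and 1 B cell receptor and 1 and 1 unfolded protein response genes. There 1 senescence gene, 1 T cell and 1 monocyte marker rose, 1 follicular and 1 homing gene fell, and 0 members passed in the other 10 lists. No list call by genotype held with an estimated correlation once the date block was fitted (lowest adjusted p = 0.104).

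The age and genotype effects were then set against each other, which asks whether loss of BAX moves young B cells as age does. The Wnt ligand gene Wnt10a was the 1 gene called in both comparisons, lower in old and in apoptosis-resistant cells. Independent lists of these sizes would share 0.01 lower and 0.05 higher genes, and 0 genes were called in opposite directions, where 0.06 would be by chance. Without young replicate 3, sensitive replicate 1, or resistant replicate 1, 2 or 3 the shared genes numbered 0, and without young replicate 1, old replicate 1 or old replicate 3 they numbered 2. With the date block 102 genes were shared in direction, 48 higher and 54 lower, against 15.39 and 18.83 for independent lists, and 40 went in opposite directions against 34.86. Across 13592 genes the fold changes had a Pearson r of 0.146 and a Spearman rho of 0.116. Of 100 splits of the libraries 41 gave an r and 32 a rho as large (permutation p = 0.41 and 0.32, both 0.41 after Benjamini-Hochberg adjustment over the pair), and genes are not independent replicates.

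The difference between the effects passed for 34 genes, 24 with a higher and 10 with a lower age effect. Mpeg1 (Entrez gene 17476, chromosome 19, 12460770 to 12465285), which encodes the pore-forming protein perforin-2, had 33.0 ± 2.23 CPM in young and 183 ± 7.13 in old wild type, but 44.1 ± 3.42 in sensitive and 42.0 ± 8.49 in resistant cells (difference 2.54 ± 0.23, adjusted p = 0.00229). Fcrl5 differed by 2.38 ± 0.24 (adjusted p = 0.00334). Rnpep, which encodes an aminopeptidase, had 44.0 ± 1.96 and 10.2 ± 2.15 CPM in young and old wild type against 43.4 ± 3.52 and 41.1 ± 1.40 in the apoptosis groups (-2.03 ± 0.24, 0.0119). Bmf (Entrez gene 171543, chromosome 2, 118528757 to 118549686) fell with age, while its level was 85.4 ± 15.2 CPM in sensitive and 236 ± 35.9 in resistant cells (-3.52 ± 0.46, 0.0195). The transcription factor gene Spic had 3.21 ± 0.57 and 12.1 ± 1.31 CPM in young and old wild type against 3.87 ± 0.43 and 2.15 ± 0.42 in the apoptosis groups (2.76 ± 0.37, 0.0195). With the date block 955 genes differed, and DESeq2 without it called 247. Leaving out 1 library gave 6 and 15 (young replicates 2 and 3), 12 and 5 (old 2 and 3), 3, 4 and 21 (sensitive 1, 2 and 3) or 2, 7 and 15 (resistant 1, 2 and 3). Of the 5 genes Bmf and Spic were each lost in 4 of these fits and Rnpep in 2, with adjusted p values up to 0.071, 0.0754 and 0.0649.

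Apoptosis-sensitive cells were set against young wild-type cells for the effect of Bak1 deficiency. This effect cannot be told apart from collection date, because the groups shared none. Nor can it be told apart from the loxP-flanked Bax gene of the sensitive cells. With edgeR 0 genes passed, 371 had an unadjusted p under 0.05, and DESeq2 called 15 and limma-voom 0. The smallest adjusted p was that of the small nucleolar RNA gene Snord35b, which lies 338584 bases from Bax (log2 fold change 2.23 ± 0.28, adjusted p = 0.0533). Slc6a16, a member of a solute transporter family that lies near Bax, was at least 56.3-fold higher in the sensitive cells (0.125). These genes were chosen after their values were seen. Of the 10 smallest p values 9 belonged to Bak1 itself or to other genes within 10 Mb of Bax or Bak1.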

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

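All tests in this part were chosen before their results were seen, apart from the fits without both libraries of 24 March or of 7 May and the counts of splits that part every date pair. Each result below is a gene or list for which the age effect and the genotype effect differed by a test of the difference itself (age effect minus genotype effect, log2 scale, edgeR or camera adjusted p).

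Among named genes the difference was 2.54 for Mpeg1 (adjusted p = 0.00229), 2.38 for Fcrl5 (0.00334), 2.76 for Spic (0.0195), 2.54 for Ccr1 (0.0411), 7.72 for Igfn1 (0.0463) and 5.17 for Itgax (0.0477), each higher with age and with a negative genotype effect that did not pass without the date block. It was -2.03 for Rnpep (0.0119), which was lower with age, and -3.52 for Bmf (0.0195), with -2.05 for age and 1.47 for genotype. It was -3.03 for Trib3 (0.0257) and 3.32 for Bax (0.0291), which follow from their genotype effects of 2.97 and -3.42. With the date block the genotype effect passed for Fcrl5 (-0.545, edgeR adjusted p = 0.0316) and for Bmf (1.471, 1.66e-05). Mpeg1 and Fcrl5 kept the call of a difference without any single library. Of 32 splits of the libraries that part every date pair, as the real one does, 4 gave at least its 34 genes. These were the real split and 3 others that all kept the real age groups and so carry an age effect, which leaves open whether chance can be excluded. The splits that also keep neither real grouping, 19 with the real one, are too few for a share under 0.05, with 1 of 19 as high as the real 34 and 0 as the highest other. Of 100 splits drawn without regard to the pairs 3 gave at least 34, and those 3 all part every pair, while most of the others part fewer. The highest, with 134 genes, kept all 4 real groups and exchanged the names of the apoptosis groups, so that it measured the sum of both effects. The next, with 40 genes, kept the age groups and mixed the apoptosis groups across dates.

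Among lists whose difference passed with an estimated correlation in the fit without the date block, the median difference was 2.11 for age-associated B cell genes (camera adjusted p = 6.06e-22, and 0.00994 with an estimated correlation), 1.48 for B-1 genes (1.2e-11, and 0.00208), 3.52 for NK cell markers (4.74e-08, and 0.00556) and 1.17 for anti-apoptotic genes (0.000789, and 0.0402). It was 0.40 for NF-kB targets (0.00016, and 0.0467 with an estimated correlation) and -0.37 for p53 targets (0.000408, and 0.0396). None of the 6 held with an estimated correlation once the date block was fitted (adjusted p = 0.0782 for B-1 genes and NK cell markers, and 0.177 for the other 4). With fry in that fit their adjusted p values ran from 0.000596 to 0.0335. Of the age-associated B cell genes 3 differed over all genes and 10 when adjusted over the list alone.

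The other list differences were lost with an estimated correlation, whose adjusted p is given after each camera adjusted p. Medians were 2.06 for T cell markers (1.72e-06, then 0.133), 0.84 for cell cycle genes (2.23e-06, then 0.37), 2.44 for stromal markers (5.45e-06, then 0.158), 2.56 for granulocyte markers (1.26e-05, then 0.363) and 1.42 for monocyte markers (0.000646, then 0.293). They were -0.35 for follicular genes (5.18e-05, then 0.139), -1.29 for germinal centre genes (0.000258, then 0.283), -0.59 for immature genes (0.00048, then 0.307) and -0.15 for ribosomal protein genes (0.0474, then 0.79). They were 2.38 for class-switched constant regions (0.0014, then 0.245), 0.70 for plasma cell genes (0.00265, then 0.491), 0.46 for plasmacytoid dendritic cell markers (0.00893, then 0.158) and 1.44 for erythroid markers (0.0497, then 0.679). Marginal zone genes had 0.36 (0.0497, then 0.222, and 0.155 with the date block). Pro-apoptotic genes had a median of 0.09 but were called lower (0.00406, then 0.158), and their mean was -0.32. The 12 other lists were not called, with camera adjusted p values of 0.221 for memory, 0.877 for interferon-stimulated, 0.877 for immediate early, 0.204 for B cell receptor, 0.762 for BAFF receptor, MHC class II and oxidative phosphorylation, 0.539 for unfolded protein response, 0.104 for senescence, 0.624 for homing, 0.749 for megakaryocyte and 0.319 for sex-linked genes.

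The first pattern weighed is the rise of age-associated B cell genes in old cells. Each date held a library of both ages, so a difference shared by the libraries of a date cannot give the age difference. Leaving out 24 March asks only whether its pair carried the rise. Without both its libraries the median kept 104% of its value. There 18 of 18 members kept over 50% of theirs (exact sign test p = 3.81e-06, with genes not independent). The medians of the date pairs were 2.02, 2.69 and 1.34, so no single pair carried the rise. Reads from monocytes and macrophages could not be excluded, because with the mean of their 10 markers as a covariate the median kept 104% without the date block and 47.7% with it, and the marker genes Lyz2 and Adgre1 stood at 61.0 ± 62.5 and 34.9 ± 14.6 CPM in old cells. Reads from T and NK cells stay open too, at 59.5% without and 53.9% with the block, with Lck at 46.6 ± 20.8 CPM in young and 40.5 ± 17.6 in old cells and 1 of the 4 NK markers, Nkg7, also on the list of age-associated genes. A sort for B220 and IgM would remove most such cells, so a true difference with age, untested here, may account for the rise as well.

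The second pattern weighed is the lower level of cell cycle genes in apoptosis-resistant cells. Reads from erythroid and granulocyte cells as the whole cause were argued against, since with the mean of their 25 markers as a covariate the median kept 86.9% without and 78% with the date block. In these fits 27 and 25 of 33 members kept over 50% of their change (exact sign test p = 0.000162 and 0.00228, with genes not independent). With the mean of 15 immature and precursor genes as a covariate the median kept 96.3% without and 151% with the block. That mean differed between resistant and sensitive cells by -0.58 to -0.28 in the date pairs. With the block it therefore nearly follows genotype, and that fit cannot decide. A different share of immature and precursor B cells was thus argued against only in the fit without the block. Each date held a library of both genotypes, so leaving out 7 May asks only whether its pair carried the lower level. Without both its libraries the median went from -1.11 to -1.53, 138% of its value. There 32 of 33 members stayed above 50% (exact sign test p = 3.96e-09, with genes not independent). The pair of 7 May therefore did not carry the lower level alone. A smaller share of dividing B cells without BAX is a hypothesis from the same data, and its list call did not hold with an estimated correlation (adjusted p = 0.0785).

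For single comparisons the 10 splits of 6 libraries are too few for a share under 0.05. For age 1 of 10 splits gave as many genes as the real 273 and the highest other had 0, and for genotype 1 of 10 gave as many as the real 6 and the highest other had 0. These other splits were 3 that part all 3 date pairs, as the real one does, and 6 that part 1 pair. With the date block the 4 splits that part every pair are also too few, with 1 of 4 as high as the real 2028 genes for age and 1 of 4 as high as the real 463 for genotype, and 0 as the highest other in both. For apoptosis-sensitive against young wild-type cells 10 of 10 splits gave as many as the real count of 0 in edgeR, and the highest other was 0. Any split reaches a count of 0, so this test could not decide. In that comparison 371 genes had an unadjusted p under 0.05 in edgeR, and DESeq2 called 15 genes and limma-voom 0. For the number of lists called with age, 3 of 10 splits gave as many as the real 16, and the highest other, which parts 1 date pair, gave 19. With an estimated correlation these counts were 4 and 0. For genotype 1 of 10 gave as many as the real 15, and the highest other gave 14 (2 and 0 with an estimated correlation). For the correlation across genes of the age and genotype fold changes, 41 of 100 splits were as large as the real 0.146 and the highest other was 0.435, and among the 16 that part every date pair 7 were as large and the highest other was 0.318, so chance could not be excluded.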

How the results depend on the processing

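The fits without both libraries of 24 March or of 7 May, and those of DESeq2, limma-voom or RLE factors with the date block, were chosen after seeing the data. Where counts moved by more than 1.5 times the cause was not tested, except that leaving out libraries leaves fewer degrees of freedom. RLE factors, upper-quartile factors, the CPM filter and leaving out immunoglobulin genes kept the counts for age, genotype and their difference within 1.5 times.

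Genes changed with age numbered 273, 735 in DESeq2, 1 with only the 6 libraries compared, 75 to 238 with 1 library left out, and 2028 with the date block (925 without 24 March). With the block they were 2059 in DESeq2, 2221 in limma-voom and 2009 with RLE factors. Genes changed by genotype numbered 6, 127 in DESeq2, 10 in limma-voom, 11 without a count filter, 0 to 5 with 1 library left out and 0 in edgeR without 7 May (139 with the block). With the block they were 463, 686 in DESeq2, 520 in limma-voom and 472 with RLE factors. Genes whose effects differed numbered 34, 247 in DESeq2, 2 to 37 with 1 library left out, 75 without 24 March (647 with the block) and 4 without 7 May (551 with the block). With the block they were 955, 1343 in DESeq2, 1088 in limma-voom and 980 with RLE factors. Apoptosis-sensitive against young wild-type cells gave 0 in edgeR, 15 in DESeq2, 3 without a count filter, 0 to 1 with 1 library left out, 3 without 24 March and 1 without 7 May.

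Genes shared in direction by age and genotype numbered 1, 23 in DESeq2, 2 without a count filter, 2 without immunoglobulin genes, 0 to 2 with 1 library left out, 4 without 24 March (73 with the block) and 0 without 7 May (26 with the block). With the block they were 102, 142 in DESeq2 and 102 with RLE factors. Those in opposite directions numbered 0, 6 in DESeq2, 0 to 1 with 1 library left out, 1 without 24 March (34 with the block) and 0 without 7 May (21 with the block). With the block they were 40, 77 in DESeq2 and 39 with RLE factors. The correlation across genes was 0.15, between -0.1 and 0.21 under the alternatives, with permutation p values of 0.2 or more.

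Bax between the apoptosis groups ranged from -3.62 to -3.07 with 1 library left out, and lost its call in 4 of 6 such fits. Bak1 in sensitive against young wild-type cells kept -2.09 in DESeq2, where it passed the threshold. With an estimated correlation, 4 of 16 list calls held for age, 2 of 15 for genotype and 6 of 21 for the difference, and with fry the calls numbered 4 for genotype and 6 for the difference. With the date block no list call held with an estimated correlation, the lowest adjusted p being 0.107, 0.104 and 0.0782. That fit left 4 residual degrees of freedom and passed no list in any comparison, so this test could not tell the lists apart. No named gene changed direction past a threshold. The direction of a list that passed the threshold in the first fit or in the alternative turned in 7 fits. A block for the date also turned 5 list directions that passed in neither fit. The camera adjusted p was 0.00454 for erythroid markers with age without young replicate 3 (highest with 1 library left out, 0.98). By genotype without sensitive replicate 3 it was 0.00251 for immediate early (range with 1 library left out 5.28e-07 to 0.0636), 0.00244 for oxidative phosphorylation (up to 0.87) and 0.000305 for ribosomal protein genes (up to 0.697). It was 0.0155 for plasmacytoid dendritic cell markers without resistant replicate 2 (up to 0.617). Without 7 May it was 0.857 for immediate early genes and 0.536 for class-switched constant regions. With 1 library left out, its date stayed in 1 group only, so a date difference entered these fits. Immediate early (2.41), oxidative phosphorylation (0.59) and ribosomal protein genes (0.64) had higher medians on 7 May, the date of sensitive replicate 3. Erythroid markers were higher on 12 April (2.84), the date of young replicate 3. Plasmacytoid dendritic cell markers had -0.26 on 31 May, with 0 genes called. Date was not tested against other causes.

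With 1 library left out, 104 of the 426 fits of genes named for age lost a call, 25 of 384 for genotype and 10 of 60 for the difference. With the date block 16 genes named for age and 21 for genotype gained a call, as did granulocyte markers with age (camera adjusted p = 0.199 without and 0.0169 with the block, where an estimated correlation gave 0.659). Calls lost with it are given in the comparisons. It was not run for sensitive against young wild-type cells, which share no date, nor were only 6 libraries fitted for the difference. Without the block the simulated recovery at a log2 fold of 1 was 15% for age and 11% for genotype. Genes with few reads were recovered less often. At a log2 fold of 2 the shares were 33.3% for age and 22.2% for genotype at a mean of 1 to 10 CPM, against 87.3% and 72.6% above that.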

Other observations

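Chosen only after the result was seen were the tests of genes near Bax and Bak1 for DNA of another strain, among equally many leading genes between collection dates, and between resistant and sensitive cells. The other test of these genes between collection dates was not.

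Collection date went with large differences in gene groups that the comparisons above do not describe. With group held constant, 7628 of 13592 genes differed between 24 March and the other wild-type dates, 3625 higher and 4003 lower, against 4014 for 11 April and 3350 for 12 April. On 24 March 46 of 77 ribosomal protein genes were lower and 18 higher (median log2 fold change -0.89), 43 of 71 oxidative phosphorylation genes were lower and 6 higher (-0.67), and 8 of 12 MHC class II genes were lower and 2 higher (-0.60). Of the 19 immediate early genes, which respond within minutes to handling and stimulation, 8 were higher and 0 lower (0.99), and 11 of 17 homing genes were lower and 1 higher (-0.72). Some markers of other cells were lower as well, 6 of 10 for monocytes (-1.99), 7 of 11 for erythroid cells (-2.25) and 5 of 7 for stromal cells (-2.59), with 0 higher. Granulocyte (-1.29), NK cell (-0.85) and plasmacytoid dendritic cell markers (-0.33) each had 1 lower and 0 higher. T cell (-0.03) and megakaryocyte markers (0.69) each had 1 higher and 0 lower. On 12 April the monocyte, erythroid and stromal markers were higher, with 0 lower, at 5 of 10 (1.75), 11 of 11 (2.84) and 6 of 7 (2.11). So were 8 of 14 granulocyte markers (3.14). Each date was 1 library per group, and with an estimated correlation no list passed (adjusted p between 0.92 and 0.967 on 24 March, and at least 0.478 on 12 April).

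In the Bak1-deficient set 3727 genes differed between 7 May and the other dates, 1745 higher and 1982 lower, against 130 for 30 May and 0 for 31 May. On 7 May 62 of 77 ribosomal protein genes (median 0.64), 44 of 71 oxidative phosphorylation genes (0.59), 23 of 33 cell cycle genes (0.88) and 10 of 19 immediate early genes (2.41) were higher. Of the follicular and resting genes 9 were lower and 1 higher (-0.36). With an estimated correlation the smallest adjusted p for a list was 0.465.

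The third pattern weighed is that genes close to Bax or Bak1 led the differences between apoptosis-sensitive and young wild-type cells, with p under 0.01 for 18 of 520 tested genes within 10 Mb of either, 3.46%, against 20 of 12662 elsewhere, 0.158% (ratio 21.9, one-sided Fisher's exact test p = 6.47e-16, with genes not independent). Of 12333 windows of this size that overlap neither, 7 had a share as high as that around Bax (3.82%) and 7 as high as that around Bak1 (3.34%). These windows were centred on single genes and overlap one another, so the counts are not of separate regions. Between resistant and sensitive cells the ratio was 2.6 near Bax (one-sided Fisher's exact test p = 0.0304) and 1.54 near either (0.0844). Date differences of the kind seen within each set were argued against, since of the 38 leading genes 18 lay this close here, but 1 between wild-type dates and 0 between Bak1-deficient dates (95% limits of the odds ratio at least 11.2, and at most 3.91 and 2.48). The share with p under 0.01 between wild-type dates, 49.4% near and 43.2% elsewhere (one-sided Fisher's exact test p = 0.0029), decides nothing because it could not exceed a ratio of 2.32, and a date difference between the sets, which shared no date, cannot be told apart from genotype. DNA of another strain carried along with the targeted genes is a candidate explanation, and the origin of the targeted alleles was not given in the sources used here.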
